A study of Mus musculus with 2 samples.

How the data were processed

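RNA from primary epidermal keratinocytes of wild-type mice and of K14-caSmad1 mice was compared on 2 two-colour Agilent whole-mouse-genome oligonucleotide arrays of 60-base probes. K14-caSmad1 mice are transgenic animals that express a constitutively active form of the transcription factor Smad1, a mediator of bone morphogenetic protein (BMP) signalling. The animals were FVB/NJ mice at day 20 after birth, per the labels. On both arrays the wild-type RNA was in the Cy3 channel and the K14-caSmad1 RNA in the Cy5 channel, per the labels, so that no dye swap was available. The labels call the arrays biological replicates 1 and 2. They do not say how many animals entered each RNA sample or of which sex these were. Total RNA was purified on columns, amplified in a single round and labelled with a kit for both dyes, per the labels' protocols. The arrays lay on 1 slide.

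The scanner files were written by Agilent Feature Extraction, per the file headers, with probe positions on the mm9 mouse genome build. They hold, per spot and channel, the mean signal intensity and the local background intensity without normalization, and processed signal intensities that were background-subtracted, detrended and dye-normalized by the software, per the file headers. They also hold flags for spots well above background, saturated spots and outliers, and a log10 ratio of the Cy5 over the Cy3 processed signal. The deposited table of the whole series holds the same log10 ratios. Set against the ratio of the processed signals it had a slope of 1 on both arrays, and it differed from it by at most 0.00396 on replicate 1 and 0.00397 on replicate 2. Its medians were 0.023 for replicate 1 and -0.01 for replicate 2, and its scale, direction and lack of further centring were therefore known.

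Each array carried 45018 spots, of which 43379 were gene spots, 1486 positive controls and 153 negative controls. The gene spots held 41174 different probes, 245 of them spotted 10 times. Background was corrected with limma's normexp method on mean signal and median local background with an offset of 50. Log2 ratios of K14-caSmad1 over wild type were then normalized within each array by loess with a span of 0.3 and weight 0 for control spots. Spots marked as feature outliers were left out on the array concerned, no gene spot was saturated (0 in every channel), and repeated spots of a probe were averaged.

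The normexp step departs from the plan in 1 point, chosen after seeing the data. On replicate 1, 36 spots were marked by the scanner software as lying on a non-uniform local background, which reached 102628 in Cy3 and 141660 in Cy5 against medians of 21 and 47. With these spots in the fit, the estimated background of replicate 1 was -466.2 in Cy3 and -407.6 in Cy5. Without them it was 181.3 and 569.3, close to the 180.2 and 561.5 of replicate 2, which had 0 such spots. The 36 spots were left out before normexp in the values reported, and the fit on all spots, as first fixed, is given as an alternative added after seeing the data.

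A probe was tested if it was well above background on both arrays in the wild-type channel or on both arrays in the K14-caSmad1 channel. This left 15110 probes. A gene with several tested probes was represented by the probe with the highest mean intensity, which gave 11752 genes. Gene names were updated through the RefSeq gene table of assembly GRCm38.p6: 24844 probes matched by accession, 6045 by symbol and 1810 by synonym, and 8475 kept the name in the file. Among 2820 genes with several tested probes, 70 had a probe below -0.5 and another above 0.5 on the log2 scale.

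Where a probe was well above background in only 1 of the channels, its change was given as a lower bound, "at least N-fold". The bound is the mean level of the bright channel over the mean, per array, of the higher of the lowest well-above-background signal and the dim probe's own signal, on loess and Aquantile normalized log2 values. Such bounds are open to dye bias. They applied to 1203 genes.

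The mean log2 ratio of both arrays was tested against 0 with limma's lmFit and eBayes and Benjamini-Hochberg adjustment at 0.05. In addition, genes were counted that differed at least 2-fold in the same direction on both arrays. Before the data were examined, 37 gene lists with 882 genes were fixed, of which 613 genes were measured. The 34 lists with 5 or more measured members were tested with camera at a preset inter-gene correlation of 0.01. The alternatives were camera with an estimated correlation, fry, and the percentile of the list's median among 10000 random lists of the same size matched on mean intensity. The genes named were fixed by rule before the data were examined. They were the 15 largest rises and 15 largest falls with an official-style symbol, Smad1, every measured member of the BMP/Smad1 target list, and up to 4 members of each other list with the largest absolute log2 ratio past the threshold.

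Before use, the fit was tested on simulated arrays with 11752 genes. It called 33 of 50 genes changed 1.2-fold, 49 of 50 changed 1.5-fold, 49 of 50 changed 2-fold and 50 of 50 changed 4-fold. There were 13 false calls among 11552 unchanged genes, and 6.7% of all calls were false. The simulated spread was drawn from limma's own variance estimate on these 2 arrays. The simulation thus checks the calculation only, and says nothing of error between animals or of data in which most genes pass.

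Alternatives fixed beforehand covered the background correction, the scanner's processed signals, median centring in place of loess, the detection filter, outlier spots, the rule for several probes, the variance model, the deposited table, a separate-channel model, other thresholds, other list tests and each array left out. No paired analysis was possible beyond the arrays themselves, because each array already compares the 2 RNA samples within itself. Calculations used R 4.3.3 with limma 3.58.1 and the package data.table (1.17.8); figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No genome sequence was used here, so whether a Smad1 probe lies within the transgene was not analysed here.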

Results

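Gene expression was measured in primary epidermal keratinocytes of wild-type mice and of K14-caSmad1 mice, in which constitutively active Smad1 is overexpressed, to find how the epidermal programme of transcription differed at day 20 after birth. There was 1 comparison, K14-caSmad1 against wild type, hybridised on 2 two-colour arrays labelled as biological replicates. In the wild-type channel 15570 and 16144 gene spots were well above background on replicates 1 and 2, and in the K14-caSmad1 channel 14412 and 15800. Across the 12297 probes measured by 1 spot in both channels, the log2 ratios of the arrays differed with an SD of 0.0961. Spots of 94 repeated probes within an array predict 0.112 for that difference from spot noise alone. For the means of these repeated probes the difference had an SD of 0.0508, above the 0.0363 that spot noise predicts. The comparisons with spot noise thus point both ways, and because the labels do not show separate animals the arrays were counted as 1 sample. Values below are means of the 2 arrays, with no error between animals. Whether the arrays carry RNA of different animals is not known, and limma's p-values are read as a measure of how well the arrays repeated. Those of camera and of the random lists set a list against other genes, with genes as the unit. They hold no error between animals either. Where members of a gene list are counted below as higher or lower without a fold, they passed limma's threshold. So did 10239 of all 11752 genes, 4800 higher and 5439 lower.

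Genes of the hair shaft were far lower in K14-caSmad1 keratinocytes, while genes of the cell cycle and, in most settings, of basal keratinocytes were higher as lists. With an estimated correlation camera called none of these lists (adjusted p = 0.982). That test had 1 residual degree of freedom, and its smallest camera p before adjustment over all lists was 0.097, for cell cycle genes. It could therefore hardly call any list, and its lack of calls, here and below, decides nothing about a list. Of 11752 genes tested, 1633 differed at least 2-fold the same way on both arrays, 480 higher and 1153 lower in K14-caSmad1. This count leaves out 36 spots of replicate 1 with a non-uniform local background, a choice made after seeing the data, and was 776 with them in the background fit. With the scanner's processed signals it was 3133 (1256 higher and 1877 lower). The balance of directions depended on the normalization: with median centring in place of loess it turned, to 1110 higher and 811 lower of 1921 genes. At 10-fold, 142 genes were lower and 1 was higher, the suprabasal keratin Krt2. The 15 largest falls held 12 keratin and keratin-associated genes of the hair shaft, led by Krtap19-9b (log2 ratio -6.32), Krtap14 (-6.01), Krtap12-1 (-5.87), Krtap31-1 (-5.81), Krtap26-1 (-5.66), Krtap1-5 (-5.52) and Krtap4-13 (-5.31). Krt33a (-5.27), Krtap6-2 (-5.26) and Krt86 (-5.20) followed. Krtap7-1 was at least 46.3-fold lower, Krtap15 at least 28.6-fold and Mlf1 at least 30.3-fold, each not well above background in K14-caSmad1. Procr, the endothelial protein C receptor, had a log2 ratio of -5.36, and Chil3, a chitinase-like protein, was at least 5.87-fold lower.

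The largest rises were led by Krt2 (log2 ratio 4.21 and 4.30 on the 2 arrays, with another probe at 3.34) and Hrnr (3.03), which encodes hornerin of the cornified layer. Cav2 (2.59), a caveolin, Cyp2g1 (2.35), Itm2b (2.19), Kazald1 (2.18), Serpinb3b (2.17) and Cpne3 (2.16) came next. Also among them were Ect2 (2.06), a regulator of cytokinesis, Dek (2.05), a chromatin protein, and Nusap1 (2.02), a spindle protein of the cell cycle list. The others were Cpe (2.06), Postn (2.01), the matrix protein periostin, Kprp (2.00), a keratinocyte proline-rich protein, and Dynlt3 (1.99), a dynein light chain. Other tested probes of Itm2b, Cpne3, Cpe and Dynlt3 gave smaller ratios of 1.17, 0.82, 0.50 and 0.80.

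**Figure D1:**
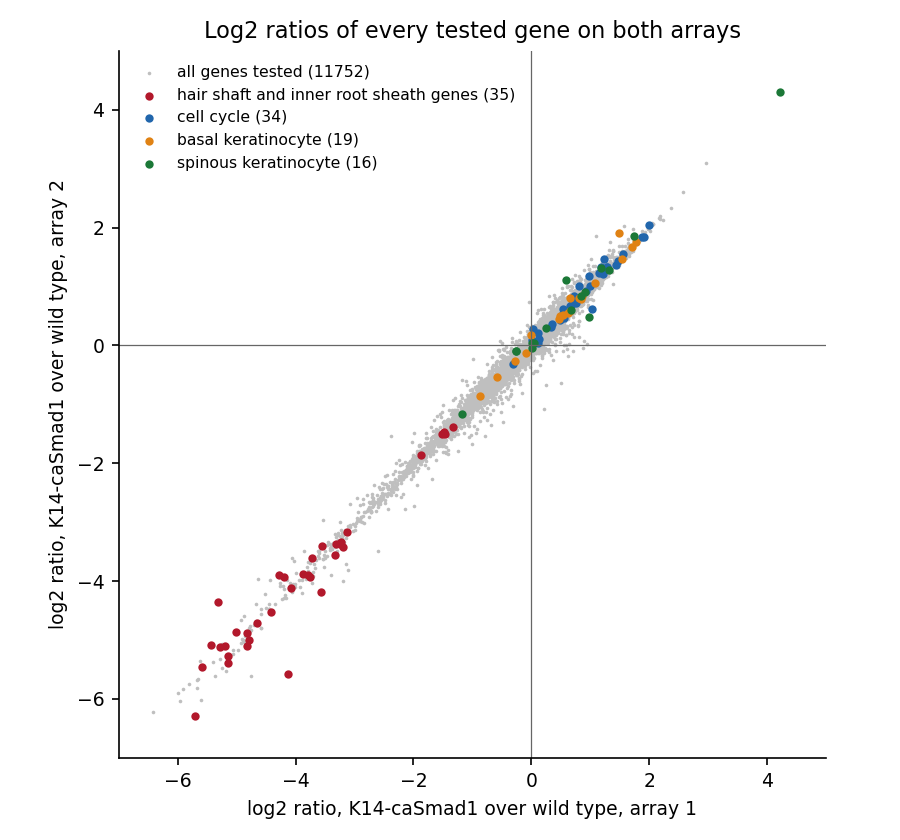
Log2 ratio of K14-caSmad1 over wild type on array 1 (x axis) against array 2 (y axis) for each of 11752 genes, with members of 4 gene lists coloured. The 35 hair shaft and inner root sheath genes lie below 0 on both arrays, and the lone green point at the upper right is Krt2 (4.21 and 4.30).

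All 35 measured hair shaft and inner root sheath genes were lower by at least 2-fold on both arrays, with a median log2 ratio of -4.07. No random list of matched intensity had so low a median (percentile 0 of 10000), and the camera adjusted p was 2.63e-10 (adjusted p = 0.982 with an estimated correlation). The list was not made up of keratins alone: trichohyalin (Tchh, -4.69), Psors1c2 (-5.15), the deiminase Padi3 (-4.09) and the hair transcription factor Hoxc13 (-1.48) were lower as well, these 4 chosen after their values were seen. In the list of 17 hair follicle stem cell and bulge genes the median was 0.04 (percentile 64.5). No bulge gene was 2-fold higher, while Col18a1 (-1.96), Foxc1 (-1.56) and Tbx1 (-1.41) were lower and Gas1 had a log2 ratio of 0.94. A second Col18a1 probe read -0.02.

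Basal keratinocyte genes had a median log2 ratio of 0.62 (percentile 99.95, camera adjusted p = 0.0174, but adjusted p = 0.982 with an estimated correlation), with 14 of 19 members past limma's threshold higher and 4 lower. With median centring the list's median was 0.93 but camera did not call it. Cav1 (1.76), the basal keratin Krt5 (1.70), Trp63 (1.69), the epithelial transcription factor p63, and the integrin subunit Itga6 (1.54 and 1.46 on the 2 arrays) differed most. A second Trp63 probe went the other way, at -0.78. Spinous keratinocyte genes had a median of 0.68 (percentile 99.9), 4 of 16 members being 2-fold higher and 1 lower, with Krt1 (1.74 and 1.86 on the 2 arrays) and the desmosomal cadherins Dsc1 (1.30, with another probe at 0.58) and Dsg1a (1.25) next to Krt2. Krt10, a member picked outside the rule for named genes, hardly differed (0.01 and 0.03 on the 2 arrays). That list did not pass camera (adjusted p = 0.0643). It was called without background subtraction, with no detection filter, with the mean of a gene's probes and with all spots in the normexp fit. With an estimated correlation it was not called.

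Cell cycle genes were higher in 30 of 34 cases by limma and lower in 1, and 12 were 2-fold higher. Their median was 0.80 (percentile 100, camera adjusted p = 2.58e-07, but adjusted p = 0.982 with an estimated correlation), or 0.75 with 6 dim members at their bound. Besides Nusap1, the members that differed most were Mcm4 (1.88), a subunit of the replicative helicase, Rrm2 (1.85), a ribonucleotide reductase subunit, and Birc5 (1.55), survivin. The 16 cell cycle inhibitors had 8 members higher and 8 lower (median -0.10, percentile 40.2), including Gadd45b (-1.30), Btg2 (-1.08, with other probes from -1.56 to -0.20), Rbl1 (0.96) and Cdkn1c, at least 1.36-fold lower.

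Chromatin regulators had a median log2 ratio of 0.41 (percentile 99.97). Of 26 members, 16 were higher and 7 lower, with Uhrf1 (1.27), Hdac1 (1.26) and Suz12 (0.92) higher and Hdac3 (-0.99) lower. That list did not pass camera (adjusted p = 0.074). Camera called it with no detection filter and with the mean of a gene's probes, but not with an estimated correlation.

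Smad1 was slightly higher, with a log2 ratio of 0.27 (0.28 and 0.26 on the 2 arrays; limma adjusted p = 0.00108) at a probe on chromosome 8, 81863015 to 81863074 (mm9). A second Smad1 probe, at 81863418 to 81863474, was not well above background in wild type and gave 0.13. The log2 ratio was 0.48 with median centring and 0.63 with the scanner's processed signals or the deposited table, and 0.16 (adjusted p = 0.689) when the normexp fit used all spots. Whether either probe reads the transgene is not known, so the value does not check the labels.

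Among 17 measured BMP/Smad1 target and feedback genes, 2 were 2-fold higher and 6 were 2-fold lower, and the list's median was -0.30 (percentile 6.41, camera adjusted p = 0.547). The median ran from -0.14 with median centring to -0.89 with the scanner's processed signals, and matched random lists called the list without replicate 1 but not with both arrays. The inhibitors of DNA binding differed in direction. Id2 (1.23), Id4 (0.81) and Id1 (0.34) were higher, and Id3 (-0.82) was lower, measured above background on 1 of the 2 K14-caSmad1 arrays. The transcription factor genes Gata3 (1.41), Dlx5 (0.81) and Hey1 (0.57, wild type above background on 1 array) were higher, whereas Msx2 (-3.19) and Dlx3 (-1.23) were lower. The pseudoreceptor gene Bambi (-3.40), noggin (Nog, -2.73) and the inhibitory Smad genes Smad6 (-2.48) and Smad7 (-0.97, above background on 1 K14-caSmad1 array) were lower. Tsc22d1 (-1.07) and Bmper (-0.27) were lower, and Runx2 was at least 1.19-fold lower. Junb had a log2 ratio of -0.13, which turned positive without background subtraction (0.03) and with median centring (0.10). A second Id2 probe gave -0.01. In the scanner's processed ratios Smad7 stood at -2.12, Smad6 at -3.82 and Hey1 at 1.44.

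**Figure D2:**
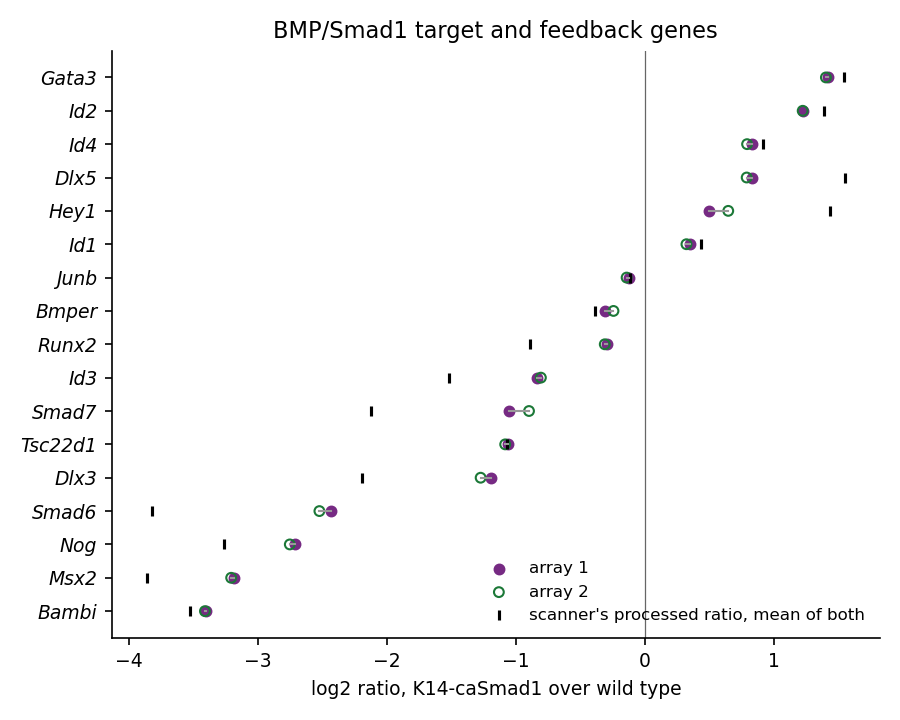
Log2 ratio of K14-caSmad1 over wild type (x axis) of the 17 measured BMP/Smad1 target and feedback genes (y axis), with a filled point for array 1, an open point for array 2 and a tick for the mean of the scanner's processed ratios. Gata3 (1.41) and Id2 (1.23) lie furthest to the right and Bambi (-3.40) furthest to the left.

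Of 14 BMP ligands, receptors and Smads, 8 were higher and 5 lower past limma's threshold (median 0.11, percentile 74.4). The ligand genes Bmp7 (-1.05), Bmp4 (-0.98) and Bmp6 (-0.95) were lower, and the extracellular modulator Twsg1 (1.02) was higher. Of 14 TGF-beta pathway genes, 8 were higher and 6 lower (median 0.23, percentile 93.7), with Tgfbi (1.07) and the receptor gene Tgfbr1 (0.97) higher and Inhbb (-1.39) and Ltbp3 (-1.17) lower.

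Cornified envelope and granular layer genes split, 7 of 43 being 2-fold higher and 8 lower (median 0.12, mean -0.04). Hrnr was higher, whereas Sprr2h (-3.61), Lce3c (-3.44) and Sprr1b (-2.31) were lower. Epidermal differentiation transcription factors also split, with 12 of 20 higher and 8 lower (median 0.32, percentile 98). Grhl1 (1.25, with another probe at 0.56) was higher, Ovol1 (-1.94, with another probe at -0.62) and Prdm1 (-1.33) were lower, and Ehf was at least 2.23-fold lower. Among 15 stress keratin and antimicrobial genes, 7 were higher and 7 lower (median 0.08). Serpinb3b and Krt6b (1.59) were higher, S100a9 was lower (-3.55, above background on 1 K14-caSmad1 array) and S100a8 was at least 4.77-fold lower.

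Of 23 barrier lipid synthesis genes, 11 were higher and 8 lower (median 0.09). The sterol synthesis gene Hmgcs1 (1.54) and the sphingolipid synthesis genes Sptlc3 (1.49) and Sptlc1 (1.28) were higher, and the ceramide synthase gene Cers4 (-1.59) was lower. Of 13 sebaceous gland genes, 4 were higher and 7 lower (median -0.08, positive with median centring and without background subtraction), including Elovl3 (-3.20), Mgst1 (-0.95, with another probe at -2.14), Cidea (0.74) and Fasn (0.52). Cell junction genes were 11 higher and 11 lower of 27 (median -0.01), but the connexin genes Gjb2 (-3.40, with another probe at -1.07) and Gjb6 (-3.06), the desmosomal Dsc2 (-2.23, with another probe at -1.33) and the tight-junction gene Cldn12 (-1.64) were each over 2-fold lower.

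In signalling lists, members moved both ways. Of 24 Wnt pathway genes, 9 were higher and 12 lower (median -0.12), with the transcription factor gene Tcf7 (-2.90, with another probe at -1.54), Wnt11 (-1.47) and Nkd2 (-1.42, with another probe at -0.26) lower and Nkd1 at least 6.27-fold lower (log2 ratios of its probes -3.84 and -2.42). Of 13 Notch pathway genes, 10 were higher and 1 lower (median 0.33, percentile 98.8, camera adjusted p = 0.0512). Camera called the list with the scanner's processed signals, the deposited table, no detection filter and an intensity trend in eBayes. With an estimated correlation it did not. Nrarp (1.30) and Maml1 (0.58) were higher, Rbpj was at least 1.41-fold higher and Numb at least 1.499-fold lower. Of 8 Hedgehog genes, 4 were higher and 3 lower (median 0.03), including Cdon (0.64), Gas1 (0.94), Ptch1 at least 1.18-fold lower and Disp1 at least 1.12-fold higher. Of 17 EGF and FGF genes, 10 were higher and 7 lower (median 0.15). The ligand Btc (1.77) and the receptor Fgfr2 (1.47, with another probe at -0.16) were higher, and Fgf22 (-1.88, with another probe at -0.81) and Tgfa (-1.74) were lower.

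Of 14 matrix remodelling and epithelial-mesenchymal transition genes, 9 were higher and 3 lower (median 0.24, percentile 96.4). The protease inhibitors Timp3 (1.64) and Timp2 (0.95) were higher, the protease gene Mmp3 was at least 1.89-fold higher, and Plat (-0.91) was lower. Interferon response genes had 3 of 15 higher and 7 lower (median -0.06), with Gbp2 (-1.82), Usp18 (-1.32), Irf9 (0.84) and Psmb8 (-0.66). Of 17 cytokine and chemokine genes, 8 were higher and 8 lower (median -0.02). Il33 (1.16) was higher, and Ccl27a (-1.48), Cxcl12 (-1.21) and Il1rn (-0.96) were lower. Immediate-early and heat shock genes had 8 of 24 higher and 9 lower (median 0.01), with Fos (-1.48), Zfp36 (-0.96), Dnajb1 (0.94, with another probe at 0.31) and Hmox1 (-0.83). Of 48 ribosomal protein genes, 17 were higher and 21 lower (median -0.02), with Rps27a (-1.42), Rps15 (-1.07) and Rpl14 (-0.79) lower and Rps23 (1.17) higher.

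Markers of several other cell types were lower in the K14-caSmad1 sample among genes passing the detection filter. That filter keeps genes seen in either channel alone, and such genes enter already differing between the channels. More gene spots were well above background in wild type (15570 and 16144 on replicates 1 and 2) than in K14-caSmad1 (14412 and 15800). The K14-caSmad1 channel was always Cy5, where negative control signals varied more. Their SD was 52.66 and 34.43 on replicates 1 and 2, against 11.1 and 10.79 in Cy3. The difference in detected spots therefore cannot be told apart from a difference between the dyes. With no detection filter 12 of 16 melanocyte, 14 of 19 endothelial, 10 of 13 adipocyte, 8 of 11 erythroid and 12 of 18 muscle markers were below 0. All 9 measured melanocyte markers were lower (median -1.04, percentile 0.07, camera adjusted p = 0.0174, but adjusted p = 0.982 with an estimated correlation), or -0.81 with 6 dim members at their bound. The median ran from -0.58 with no detection filter to -2.37 with the scanner's processed signals, and camera did not call the list with all spots in the normexp fit. With both channels required above background, 3 melanocyte and 4 erythroid markers remained, too few for the list test. Pmel (-1.28) and Gpnmb (-1.16) were among them, with Mitf at least 1.76-fold and Mlana at least 1.91-fold lower. All 6 erythroid markers were lower (median -1.14, percentile 0.25, camera adjusted p = 0.0364, but adjusted p = 0.982 with an estimated correlation), with Eraf (-4.07), Car2 (-2.49), the globin gene Hba-a1 (-1.39) and Alas2, at least 1.78-fold lower. With no detection filter the erythroid median was -0.16 over 11 members and camera did not call the list. All 5 endothelial markers were lower (median -0.90, percentile 0.29, camera adjusted p = 0.0702), with Prox1 (-1.09) and Flt1, Vwf and Esam at least 1.61, 1.86 and 1.29-fold lower. Camera called the endothelial list with median centring and with no detection filter, but not with an estimated correlation. All 4 measured members of the adipocyte list were lower (median -1.10), with Fabp4 (-4.67, with another probe at -5.53), Acp5 (-0.53), Lipe at least 2.42-fold and Lpl at least 1.28-fold lower. The 3 skeletal muscle markers Eno3 (-0.98), Mylpf (-0.61) and Tnni2 (-0.40) were lower as well. So were the 2 measured members of the mast cell list, Srgn (-0.70) and Kit, at least 1.36-fold lower. Kit is also in the melanocyte list. Over the alternatives the median ran from -0.18 to -2.87 for adipocyte, -0.13 to -1.78 for endothelial, -0.08 to -0.94 for muscle and -0.05 to -1.97 for mast cell markers, in each case smallest with no detection filter.

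Fibroblast markers split, 3 of 11 being 2-fold higher and 4 lower (median -0.56, percentile 0.79). The median was -1.77 with the scanner's processed signals and turned to 1.21, over 5 members, when both channels had to be above background. Postn was higher and Dpp4 (-2.04) lower, and the collagen genes Col3a1 and Col1a1 were at least 3.15-fold and 2.41-fold lower. Merkel cell markers had 1 of 6 higher and 4 lower (median -0.66, from -0.01 with no detection filter to -1.46 with the deposited table), with Krt18 (-1.70), Cck (-0.62), and Krt8 and Piezo2 at least 1.61-fold and 1.06-fold lower. Of 14 T cell markers, 7 were higher and 5 lower (median 0.15), with Ptprc (0.90), Cd3g (0.88), Cd4 (-2.98 and -3.01 on the 2 arrays) and Ctsw (-1.02). Of 12 Langerhans and antigen-presenting cell markers, 7 were higher and 1 lower (median 0.11), with H2-DMb1 (0.90, with another probe at 0.18), the Langerhans cell gene Cd207 (0.86), H2-DMa (0.84) and Itgax, at least 1.23-fold lower. Macrophage and neutrophil markers had 5 of 11 higher and 4 lower (median 0.01), including Adgre1 (1.45), Ctss (1.40), Cd68 at least 2.05-fold and Mpo at least 1.18-fold lower. Nerve and Schwann cell markers had 3 of 7 higher and 3 lower (median 0.00), including Tubb3 (-2.51), Pmp22 (1.37), Mbp (0.62) and S100b (-0.45).

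**Figure D3:**
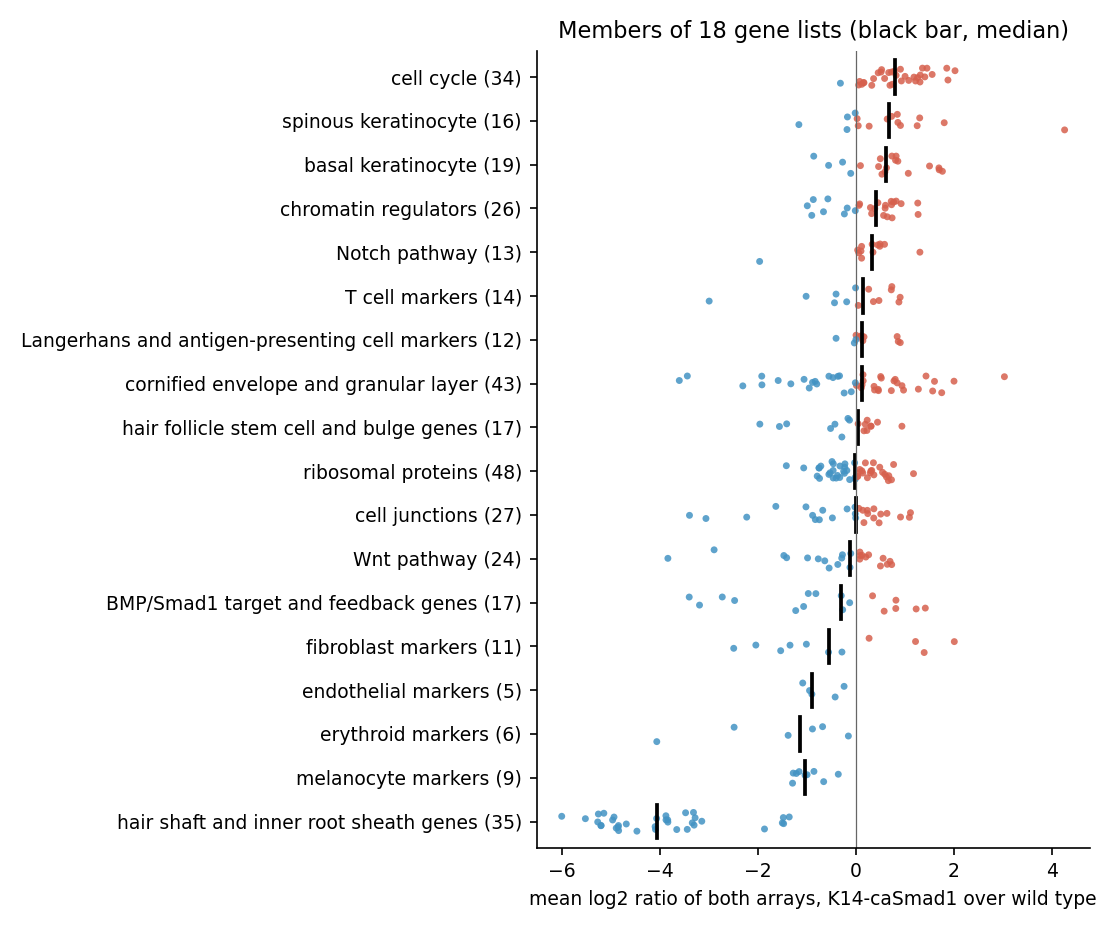
Mean log2 ratio of both arrays, K14-caSmad1 over wild type (x axis), for each measured member of 18 gene lists (y axis, number of members in parentheses), red when above 0 and blue when below 0, with a black bar at the median. The medians run from -4.07 for hair shaft and inner root sheath genes to 0.80 for cell cycle genes.

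By limma, 10239 of 11752 genes passed the threshold, 4800 higher and 5439 lower, a count that cannot be read as a spread between animals. With the normexp fit on all spots, as first fixed, the count was 3269 (1590 higher and 1679 lower). With median centring the split of calls was 6887 higher and 3577 lower, and the median of all genes moved by 0.25 on the log2 scale. The log2 ratios of the arrays correlated across genes at Pearson's r = 0.993 and Spearman's rho = 0.988, where genes are not independent replicates.

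Of 34 lists, camera called 5: hair shaft and inner root sheath, cell cycle, basal keratinocyte, melanocyte and erythroid. With an estimated correlation none was called (0 lists), in a design whose 1 residual degree of freedom left that test hardly able to call any list. Matched random lists called 8, adding spinous keratinocyte genes, chromatin regulators and endothelial markers, and fry, which tests only whether genes move one way on balance, called 28. Median and mean differed in sign for the lists of BMP ligands, cornified envelope, stress keratins, bulge, EGF and FGF, T cell and immediate-early genes (median above 0, mean below 0). For cell cycle inhibitors, cell junctions and nerve markers the median was below 0 while camera pointed up, and for immediate-early genes the median was above 0 while camera pointed down. Adjusted over the list alone, the counts of members past the threshold were the same for 34 of the 37 lists. They were 22 higher in place of 21 for cornified envelope genes, 17 in place of 16 for chromatin regulators and 6 in place of 7 for Langerhans markers. Across genes, the log2 ratio fell with the GC content of the probe (Spearman's rho = -0.26). Both arrays had the same dye orientation, so a gene-specific dye effect cannot be told from genotype.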

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

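The arrays carry spike-in control probes that the comparison of genes does not use. For a22 and a104, 2 of the 10 spike-in probes, 32 of 32 spots were well above background in both channels of both arrays. Others gave little or no signal. For a107 the count was 0 of 32 spots in every channel, and for a97 it was at most 2. For a20 it was 32 in Cy3 but at most 1 in Cy5. For observed against expected spike-in log ratios the scanner software gave a slope of -0.118 on replicate 1 and -0.103 on replicate 2. Equal observed and expected log ratios would give a slope of 1, so the observed ratios did not follow the expected ones. With several spike-in probes nearly without signal, the slope cannot show how well the ratios of genes were measured. The software's correlation statistic was low, at 0.083 and 0.0559. Its sign differs from that of the slope, and how it is computed was not known here. The mean log2 ratio of K14-caSmad1 over wild type was -1.09 and -1.07 for a22, and -0.18 and -0.14 for a104.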

How the results depend on the processing

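The fit on all spots, each gene's own spread, the test against a 2-fold minimum and the random lists on a lone array were chosen after the data were seen. Of 2102 values of the other named genes under the alternatives, 2067 were labelled the same. With both arrays this means the same direction and side of the threshold. For the 178 values without replicate 1 and the 178 without replicate 2 there is no threshold. There 176 and 177 lay within the SD of the 2 arrays, which is bound to hold unless the gene's probe changes, and 3 moved. Of the rest, 30 kept direction but missed the threshold (29 with all spots in the normexp fit, 1 with median centring). The last 2 turned sign, both of Junb, at 0.0299 without background subtraction and 0.10 with median centring.

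The count past the threshold moved to 17755 with no detection filter, 3269 with all spots in the normexp fit, 2333 with each gene's own spread and 1292 against a 2-fold minimum, and otherwise lay between 8636 and 10619. The count at 2-fold moved to 3133 with the scanner's processed signals, 3129 with the deposited table, 776 with all spots and 3843 at 1.5-fold. It was 1776 to 1782 when either array was left out. Of the 1633 genes, 1628 kept their sign with the processed signals and 1631 with all spots. Smad1 missed the threshold with all spots (0.16) and was 0.26 to 0.28 with either array left out. The correlation moved to 0.973 with no detection filter and 0.892 with all spots. The lists called were 8 with no detection filter, 3 with both channels above background, 0 with an estimated correlation, 28 with fry, 8 with matched random lists, and 8 to 10 with matched random lists when either array was left out. With a lone array no residual degree of freedom remains, so neither limma's count nor camera could be run on it.

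Signal over background limits the size of changes in 1203 genes that were dim on both arrays of a channel. Others were dim on 1 array. With both channels required above background on both arrays, 9931 genes remained, and 1323 of the 1633 genes at 2-fold. The processed signals moved 1665 genes by over 1.5-fold, each to a larger change. The cause of the changes was not tested. The median of the fibroblast list turned from -0.56 to 1.21 with both channels required above background, which leaves out members dim in 1 channel. With at least 1 alternative the sign of the median also turned for the lists of epidermal transcription factors, bulge, sebaceous, Hedgehog, cell cycle inhibitor, junction, cytokine, ribosomal and nerve genes. For Wnt and interferon genes it turned only with median centring, and not relative to the median of all genes.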

Other observations

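The families below and the tests of keratin probes, follicles and Y-linked genes were chosen after their results were seen; the tests of probe GC content and probe position were set before theirs.

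All 39 tested keratin-associated protein genes were at least 2-fold lower in K14-caSmad1, from -6.32 (Krtap19-9b) to -2.93 (Krtap19-2), with a median log2 ratio of -4.70. Families are given with the percentile of their median among random lists matched on intensity and GC content, here 0. They were taken by gene symbol alone. The S100 family thus holds S100pbp, the claudins hold Cldnd1, and the high mobility group family holds Hmgb1-ps7 and Hmgb1-rs17. The peptidyl arginine deiminases were lower in 3 of 3 cases (percentile 0.34): Padi1 (-4.49), Padi3 (-4.09) and Padi4 (-2.26). Small proline-rich proteins were lower in 8 of 9 cases (median -1.33, percentile 0.03). Late cornified envelope genes were higher in 10 of 13, with a median of 0.37 that lay within the spread of matched lists (percentile 93.86). Connexin genes were lower in 7 of 9 (percentile 0.17), with Gja3 at least 26.03-fold, Gja5 at least 9.03-fold, and Gjb2 (-3.40, another probe -1.07) and Gjb6 (-3.06) lowest. Cathepsin genes were lower in 10 of 13 (percentile 2.15), led by Ctse (-3.72), and Ctss (1.40) was highest.

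Heterogeneous nuclear ribonucleoproteins were higher in 18 of 19 cases (median 0.99, percentile 100), led by Hnrnpf (1.79), Hnrnpm (1.64) and Hnrnpab (1.59, another probe 0.16), with Hnrnpa0 (-0.20) the exception. High mobility group proteins were higher in 9 of 10 cases (median 0.90, percentile 99.96), led by Hmgn2 (1.52) and Hmgn1 (1.47), and minichromosome maintenance proteins were higher on both arrays in 8 of 9 (median 0.67, percentile 99.75), Mcm9 (0.01) and Mcm7 (0.05) hardly differing from 0. Centromere proteins were higher in 13 of 16 (median 0.61, percentile 100). Cytochrome c oxidase subunits were lower on both arrays in 12 of 13, by less (median -0.45, percentile 6.29, within the spread of matched lists). With the scanner's processed signals each of these families kept the sign of its median. Of 15 families examined, the others were keratins (26 of 37 lower, percentile 0), S100 proteins (11 of 14 lower, percentile 4.1), phospholipases A2 (6 of 11 lower, percentile 13.76) and claudins (5 of 9 lower, percentile 71.22), the claudin median turning from -0.01 to 0.09 with the processed signals.

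Hair shaft genes were lower while cell cycle and basal keratinocyte genes were higher. Cross-hybridisation among keratin and keratin-associated probes is argued against as the whole cause, since the 6 hair genes outside both families were all lower, with a median of -4.39. These 6 genes cannot show whether the keratin probes read each other's transcripts. A labelling effect tied to base composition is argued against as the whole cause: among lists matched on intensity and GC content, the percentile of the median was 0 for hair genes, 100 for cell cycle genes and 99.98 for basal keratinocyte genes. A smaller number of hair follicles, or an earlier or later hair cycle stage, in the transgenic sample could give the fall, and lower melanocyte markers go with it (median -1.04). Bulge genes went both ways (8 higher and 8 lower), markers of cells not particular to the follicle were also lower (erythroid -1.14, adipocyte -1.10, endothelial -0.90, but -0.16, -0.18 and -0.13 with no detection filter, against -0.58 for melanocyte markers), and the design, with no dye swap, cannot separate sample makeup, an effect of the transgene on the same cells and a gene-specific dye effect.

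Y-linked genes were higher in K14-caSmad1. Ddx3y (1.65 and 1.70), Eif2s3y (0.79 and 0.89) and Kdm5d (0.46 and 0.43) were higher on the 2 arrays, the lowest mean being 0.446. Each Y-linked gene exceeded the brightest probe of its X-linked partner by at least 0.703 on both arrays, which argues against partner transcripts as the source of the Ddx3y and Kdm5d signals, also against the partners' highest probes (differences of 1.08 and 0.91). For Eif2s3y the difference from the highest of 3 partner probes was 0.17, under the limit of 0.2, so that the partner could account for its value. A larger share of male animals in the transgenic sample may account for the values, but none of the 4 Xist probes or the 3 Uty probes was well above background (0 each), so that the counterpart was not measured and the sex of the animals stays open.

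Different probes of 1 gene gave different log2 ratios. Over 2091 genes with an ordered pair of bright probes, the ratio of the 3' probe exceeded that of the 5' probe by a median of 0.0767 (95% bootstrap interval over genes 0.045 to 0.113), against a median absolute difference of 0.386. Of the 52 ordered pairs among the 70 genes with opposed probes, 39 were higher at the 3' end and 13 at the 5' end. A difference between the samples in RNA length, by degradation or amplification, could shift values in this way. The rule set beforehand argued against it if the median lay within the limit of 0.1 on both arrays. The medians were 0.0745 on replicate 1 and 0.0801 on replicate 2, so that rule was met. The interval, a condition added to that rule, reaches past 0.1. A small shift therefore stays open and cannot be told apart from different transcript ends.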
